A study of Mus musculus with 30 samples.

How the data were processed

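Total RNA of mouse cardiac myocytes was measured in 30 libraries, 5 in each of 6 groups set by genotype, age and exercise. Per the labels' protocols, RNA was isolated with the miRNAeasy mini kit, depleted of ribosomal RNA, and made into strand-specific paired-end libraries with the TruSeq RNA Library Prep Kit v2. Per the submitters' processing notes, Trim Galore, HISAT2, featureCounts and the build mm10 were used, without versions. The deposited values are raw counts per gene, joined by the authors into 1 table of all 30 libraries. The sources used here do not state the annotation release, the strand setting or any filter, so overlapping genes, antisense genes and near-identical copies could share reads, and values of such genes are uncertain.

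The table held 52573 entries, of which 52550 were genes and 23 were spike-in controls, which were not analysed as genes. Gene symbols that a spreadsheet had turned into dates were restored from the gene IDs for 26 genes. Positions came from GENCODE mouse release M21 on the same build (GRCm38), which held 52403 of the gene IDs. A gene with no read in a group was given a floor of 3 counts over the whole group for a lower bound on its fold change. The labels do not say whether the replicates are separate animals.

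Genes were filtered with filterByExpr over the 6 groups, which left 15587 genes, and scaled with TMM factors. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with robust fitting over all 30 libraries, 24 residual degrees of freedom and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. CPM values are counts per 10⁶ on the TMM-scaled library sizes, and log2 CPM adds a prior count of 2. Fold changes are printed as log2 values with their standard error (SE), which is the log2 value divided by the square root of F, and n is 5 libraries per group throughout.

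The 10 comparisons were genotype at 3 months, at 6 months with regular activity and at 6 months with exercise, exercise in each genotype, exercised heterozygotes against regular-activity wild type, age in each genotype, and the interactions of genotype with exercise and with age. The groups, the comparisons, the 40 gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule named Dsp in every comparison. It also took up to 8 called genes in each direction with the largest fold change, a mean log2 CPM of at least 1, a symbol that is not a provisional one, and at least 9 of the 10 libraries on their own group's side of the midpoint of both group means. In addition it took up to 4 members of each list with the smallest p, and Nppa, Nppb, Myh6, Myh7, Jup, Pkp2, Dsg2, Dsc2 and Gja1 with the desmosome and wall stress lists. Any other gene named was chosen after its values were seen. Some genes that the rule takes are not reported here.

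Gene lists were tested with camera on log2 CPM at a preset correlation of 0.01, adjusted over the lists of each comparison, and again with an estimated correlation and with fry. The lists covered the desmosome and intercalated disc, fetal and wall stress genes, sarcomere, ion channels and calcium handling, oxidative phosphorylation, mitochondrially encoded transcripts, fatty acid oxidation, TCA cycle and branched-chain amino acids, glycolysis, adipogenesis and extracellular matrix. Signalling and stress lists were TGF-beta and BMP, Wnt, Hippo and YAP, inflammation, interferon, p53, the unfolded protein response, heat shock, oxidative stress, immediate early genes, circadian clock, cell cycle, angiogenesis and epigenetic regulators. RNA lists were ribosomal proteins, nuclear-retained and small RNA, and replication-dependent histones. Marker lists covered fibroblast, endothelial, pericyte, macrophage, lymphocyte and neutrophil, erythroid, adipocyte, Schwann, epicardial, atrial, ventricular myocyte and sex-linked genes. Of 984 list symbols, 975 matched the table, and a list needed at least 5 tested genes.

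Alternatives fixed in advance were DESeq2 size factors in edgeR, no low-count filter, a replicate block, removal of mitochondrial and the 10 most abundant other genes, 1 surrogate variable (sva 3.50.0), a fit of each comparison's own groups, limma-voom with quality weights, the DESeq2 Wald test (DESeq2 1.42.0), leaving out each library, a threshold of 0.01, and windows of 5 and 50 Mb around Dsp in place of 20 Mb. Alternatives chosen after seeing the data were removal of trends on GC content and length, Xist as a covariate, leaving out the library labelled heterozygote 3 at 3 months from the other fits, leaving out heterozygotes 1 and 2 at 3 months, leaving out exercised wild type 1 and heterozygote 4, and a held-out comparison of the 100 top genes.

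The test was checked on simulated counts for the 6-month genotype comparison with 15011 genes. Of changed genes with a mean log2 CPM of at least 1, it recovered 28.6% at 1.5-fold and 93.0% at 4-fold, and it called 2 of 14784 unchanged genes. Splits of the same libraries into other groups were drawn 100 times per comparison with a fixed seed.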

Results

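RNA levels in cardiac myocytes were measured in wild-type mice and in mice of the genotype Myh6-Cre:DspW/F, called heterozygotes here, which the series title describes as haplo-insufficient for desmoplakin. Myh6-Cre drives Cre recombinase in cardiac myocytes, and Dsp encodes desmoplakin, which ties desmosomes to intermediate filaments. The labels do not say whether the wild-type mice carry Cre, so Cre and the Dsp allele cannot be separated. There were 6 groups of 5 libraries, at 3 months, at 6 months with regular activity, and at 6 months after 3 months of endurance treadmill exercise. Total counts, in units of 10⁶, averaged 15.7 ± 1.19 (SD, n = 5) in wild type and 15.1 ± 4.99 in heterozygotes at 3 months. They averaged 19.9 ± 1.82 and 20.2 ± 2.79 at 6 months, and 17.9 ± 3.14 and 15.7 ± 1.76 in the exercised groups. Transcripts of the mitochondrial genome took 12.3% ± 1.77 and 10.99% ± 2.15 of the counts at 3 months, 15.6% ± 1.68 and 19.9% ± 6.32 at 6 months, and 28.3% ± 10.6 and 29.4% ± 6.12 with exercise, in wild type and heterozygotes. Ribosomal RNA took 1.63% ± 0.301 and 2.10% ± 1.01, 1.82% ± 0.488 and 3.52% ± 2.03, and 5.31% ± 1.41 and 5.12% ± 0.877 in the same order. The table gives a value for 3 of the 23 spike-in controls in the 3-month libraries, for 18 in the 6-month regular-activity libraries (11 in wild type 5) and for 0 in the exercised libraries. The sets of libraries therefore follow age and exercise, and a separate processing of these sets cannot be told apart from age or exercise. Each set holds both genotypes. Libraries with a high Xist level numbered 3 of 5 in both groups at 3 months, 2 of 5 in both at 6 months and 1 of 5 in both exercised groups. Of these, wild type 4 at 3 months (Xist 71.7 CPM) and wild types 2 and 5 at 6 months (138.6 and 145.2) also had Y-linked transcripts (5.69, 2.40 and 2.87 CPM, at most 0.295 in the others). A mix of samples in these 3 libraries was not tested.

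Dsp (ENSMUSG00000054889, GRCm38 chromosome 13, 38151294 to 38198577) was 1.84-fold lower in exercised heterozygotes than in exercised wild type. The means were 847.8 ± 90.5 and 1561 ± 428 CPM (SD, n = 5, log2 fold change -0.88, SE 0.193, edgeR adjusted p = 0.0287, 9 of 10 libraries on their group's side). Without exercise the mean was also below wild type, at 765 ± 213 against 1079 ± 295 CPM at 3 months and 625.6 ± 41.1 against 784 ± 173 CPM at 6 months. Neither of these differences passed the test (log2 fold change -0.50, SE 0.192, edgeR adjusted p = 0.312; and -0.33, SE 0.191, edgeR adjusted p = 0.657). In wild type, Dsp rose 1.99-fold with exercise (log2 fold change 0.99, SE 0.193, edgeR adjusted p = 0.00106, 9 of 10 libraries). In heterozygotes its log2 fold change with exercise was 0.44 (SE 0.191, edgeR adjusted p = 0.162), and the difference between both exercise effects was -0.56 (SE 0.27, edgeR adjusted p = 0.999). With age it was -0.46 in wild type (edgeR adjusted p = 0.297) and -0.29 in heterozygotes (0.426), with an interaction of 0.17 (0.905). A count over the whole gene includes reads from a recombined allele outside its deleted part. At 3 months, 7 of 10 libraries lay on their group's side: the library labelled heterozygote 3 had 1126 CPM, the other heterozygotes 573 to 740.7, and wild types 1 and 4 759.8 and 752.3. The call in exercised mice was lost when exercised wild type 2 (edgeR adjusted p = 0.109), 3 (0.0773) or 4 (0.0954), or exercised heterozygote 2 (0.0617), 3 (0.0528), 4 (0.0896) or 5 (0.0578) was left out.

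**Figure D1:**
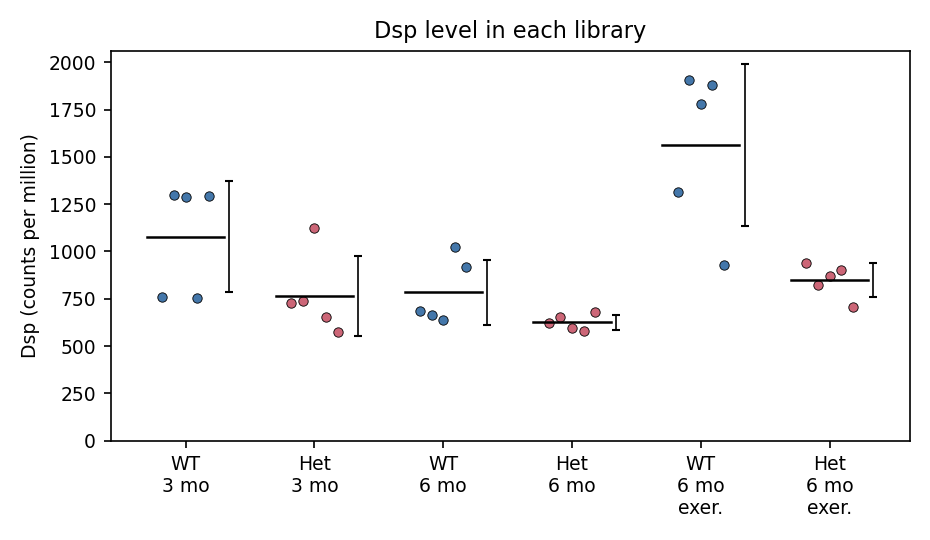
Dsp level in CPM (y axis) in each of the 30 libraries (points) of the 6 groups (x axis), with the group mean (bar) and SD (whisker). Exercised wild-type libraries had 928.1 to 1907 CPM and exercised heterozygotes 705.2 to 938.9.

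The young heart was compared between genotypes at 3 months. Ndnf (ENSMUSG00000049001), which encodes a secreted neurotrophic and vascular factor, rose 3.49-fold in heterozygotes, from 7.48 ± 1.67 to 26.1 ± 10.6 CPM (SD, n = 5, log2 fold change 1.80, SE 0.249, edgeR adjusted p = 0.000735, 9 of 10 libraries). Phlda3 (ENSMUSG00000041801), a p53 target that restrains Akt, rose 5.10-fold, from 2.15 ± 0.723 to 11.01 ± 6.32 CPM (log2 fold change 2.35, SE 0.453, edgeR adjusted p = 0.0409). Smaller rises were called for Stambpl1 (log2 fold change 1.32, a deubiquitinase), Rpl13a (1.26, which has near-identical copies), Snapc5 (0.93), Sfxn1 (0.90, a mitochondrial serine carrier), the lysosomal phosphatase gene Acp2 (0.58) and Abi2 (0.54), all at an edgeR adjusted p of 0.0498. Falls were called for Mettl26 (-0.68), Syde1 (-0.65), the coactivator gene Rbm14 (-0.58) and Cnot11 (-0.51), a subunit of the CCR4-NOT deadenylase, at the same edgeR adjusted p. In all, 26 genes rose and 4 fell of 15587 tested, and 14 of these 30 were protein-coding. Most of the others were small RNAs such as Rny1 and Rnu12, named after their values were seen, and heterozygotes 1 and 2 had a small-RNA share of 0.864% and 0.755% against 0.0927% to 0.138% in the other 3-month libraries. In the p53 list, 18 of 24 tested genes were higher (median log2 fold change 0.21, camera adjusted p = 0.0172, adjusted p = 0.417 with an estimated correlation). Phlda3 was called in it over all genes, 2 genes when adjusted over the list alone, and Aen (log2 fold change 0.45), Ccnd2 (0.54) and Eda2r (0.99) were not called over all genes. The call for the p53 list was lost without wild type 1 (camera adjusted p = 0.101) and without 3 other libraries, wild type 4, heterozygote 2 and heterozygote 5. All 20 endothelial markers were lower (median -0.55, camera adjusted p = 4.69e-05, adjusted p = 0.916 with an estimated correlation). Cldn5, a tight junction gene, was at -1.48 (SE 0.424), Robo4 at -0.80, Erg at -0.78 and Cdh5 at -0.66, with 0 genes called over all genes and 1 when adjusted over the list alone.

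Most 3-month calls lay near the threshold. Their number fell from 30 to 1 without wild type 3, heterozygote 1 or heterozygote 2, and to 3, 6, 4 and 2 without wild types 1, 2, 4 and 5. It rose to 70 without heterozygote 4 or the library labelled heterozygote 3 and to 74 without heterozygote 5. Ndnf was called in all 10 of these fits, and Phlda3 was lost in 7, with a highest edgeR adjusted p of 0.104 without heterozygote 2. Each of the other 10 named genes was lost in 6 to 9 of them, with a highest edgeR adjusted p from 0.119 (Acp2, Abi2 and Syde1, without wild type 5) to 0.198 (Cnot11, without heterozygote 2). The library labelled heterozygote 3 stood at wild-type level for several of these genes: 8.82 CPM of Ndnf against 25.5 to 35.4 in the other heterozygotes, and 2.46 CPM of Phlda3 against 7.76 to 17.6. Dmd, Exoc2, Dcakd and Ctnna3 had log2 fold changes of -0.62, -0.79, -0.72 and -0.69 at 3 months and were not called (edgeR adjusted p = 0.18, 0.0734, 0.0626 and 0.0894). For Dmd, Exoc2 and Ctnna3, heterozygotes 1, 2, 4 and 5 lay below every wild type, and all 4 genes were called without the library labelled heterozygote 3 (edgeR adjusted p = 0.00118, 0.00321, 0.00951 and 0.0144).

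At 6 months with regular activity, heterozygotes had less mRNA for Dmd and Ctnna3. Dmd (ENSMUSG00000045103, chromosome X), which encodes dystrophin, fell 2.33-fold, from 304.5 ± 20.9 to 130.7 ± 24.3 CPM (SD, n = 5, log2 fold change -1.22, SE 0.19, edgeR adjusted p = 0.00171, 10 of 10 libraries). Ctnna3 (ENSMUSG00000060843, chromosome 10), the alpha-T-catenin of intercalated discs, fell 2.09-fold, from 54.8 ± 6.19 to 26.2 ± 3.29 CPM (-1.06, SE 0.173, edgeR adjusted p = 0.00232). Exoc2, a subunit of the exocyst, fell 2.43-fold (-1.28, SE 0.191, edgeR adjusted p = 0.000876). Alox5, the leukotriene-forming lipoxygenase, fell 3.65-fold (-1.87, SE 0.348, edgeR adjusted p = 0.0207), and Amy1, an amylase gene with near-identical copies, 3.38-fold (-1.76, SE 0.336, edgeR adjusted p = 0.0207). Prrg1 (-0.91, edgeR adjusted p = 0.0496), Dcakd (-0.83, 0.0315) and Apbb1 (-0.74, 0.0244) also fell. Ndnf rose 3.15-fold, from 8.49 ± 2.32 to 26.8 ± 4.86 CPM (1.65, SE 0.244, edgeR adjusted p = 0.000876). Pcolce, an enhancer of procollagen processing, rose 2.34-fold, from 19.8 ± 1.62 to 46.4 ± 4.97 CPM (1.23, SE 0.183, edgeR adjusted p = 0.000876). Among other called genes, chosen after their values were seen, Irs4 had 0 counts in wild type and 43 in heterozygotes, at least 13.8-fold higher with a floor of 3 counts over the group, and Jph1, a junctophilin, fell by 0.54 and Ak4 by 0.57. In all, 5 genes rose and 16 fell, and 20 of the 21 were protein-coding.

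The 21 calls fell to 6 without heterozygote 1 or 5, 7 without heterozygote 4, 10 without heterozygote 3, 11 without wild type 2 or 5, and 12 without wild type 1 or 4. Ndnf, Pcolce, Exoc2, Dmd and Ctnna3 were called in all 10 of the leave-one-out fits. Alox5 was lost in 4 and Amy1 in 3 (highest edgeR adjusted p = 0.138), Apbb1 in 6 (0.162), Dcakd in 8 (0.173) and Prrg1 in 8 (0.233), each highest without heterozygote 5.

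**Figure D2:**
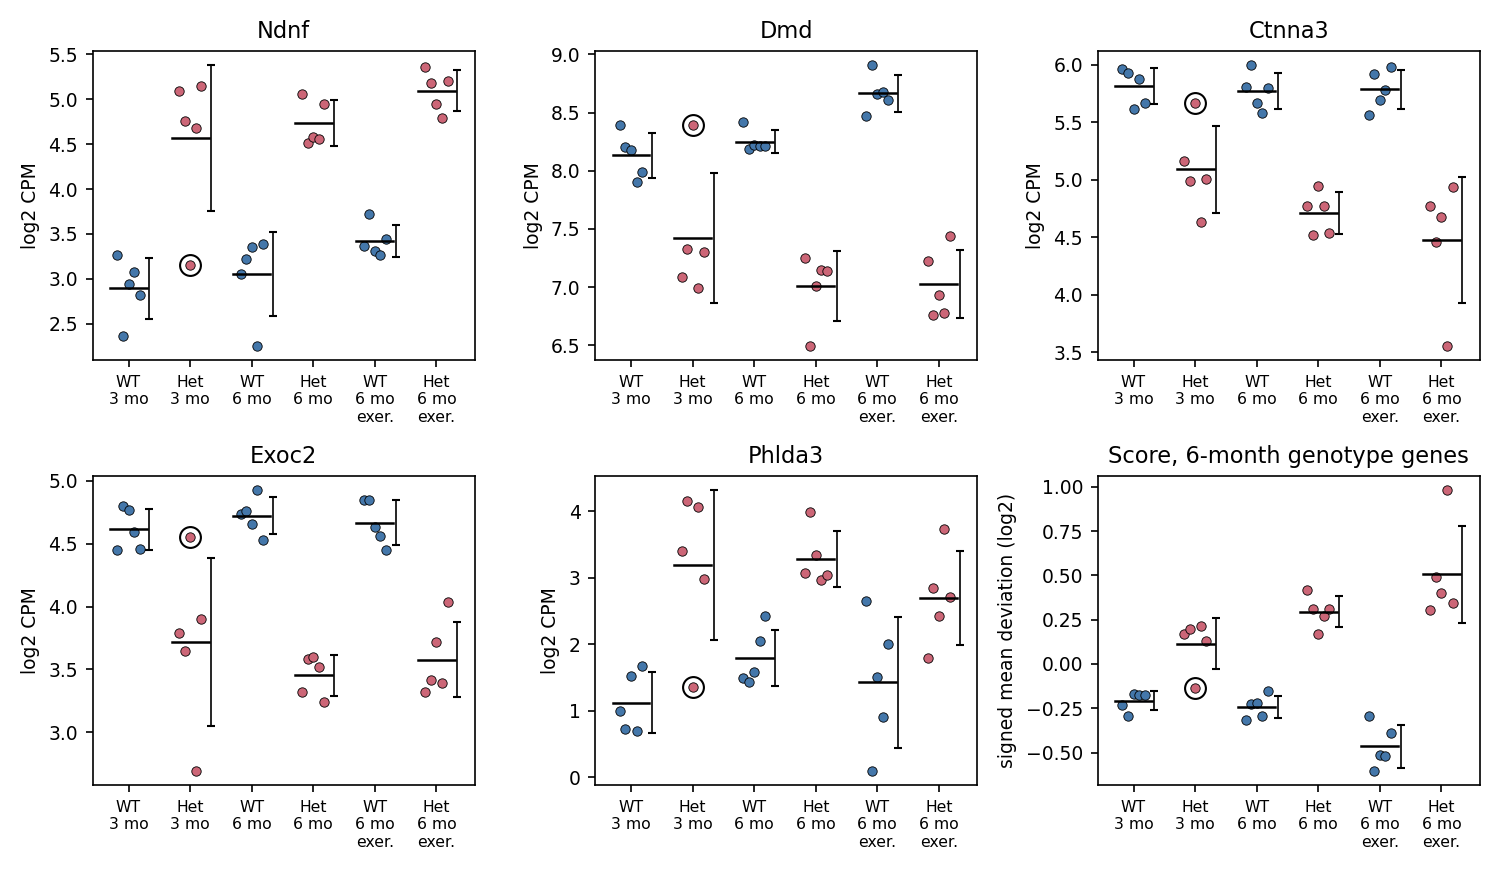
Level of Ndnf, Dmd, Ctnna3, Exoc2 and Phlda3 in log2 CPM and a signed score over 61 of the genes called for genotype at 6 months (y axes) in each library (points) by group (x axes), with group mean (bar) and SD (whisker). The library labelled heterozygote 3 at 3 months is circled.

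Gene groups of connective tissue and immune cells were higher in heterozygotes at 6 months. In the extracellular matrix list, 38 of 39 tested genes were higher, with a median log2 fold change of 0.93 (camera adjusted p = 4.07e-19, adjusted p = 0.247 with an estimated correlation). Its members with the smallest p were the protease inhibitor gene Timp1 (log2 fold change 2.59, SE 0.573), the collagen genes Col1a1 (1.38, SE 0.378) and Col3a1 (1.47, SE 0.429), and Tnc (3.89, SE 1.08). Of the list, 0 genes were called over all genes and 8 when adjusted over the list alone. All 15 macrophage and monocyte markers were higher (median 1.41, camera adjusted p = 4.19e-12, adjusted p = 0.132 with an estimated correlation). Among them were Lyz2 (1.73), Csf1r (1.17), Adgre1 (1.40) and Mrc1 (1.83), with 0 called over all genes and 8 over the list alone. Of 17 fibroblast markers, 16 were higher (median 0.77, camera adjusted p = 4.05e-07, adjusted p = 0.276 with an estimated correlation), and Fbln1 was lower (-0.93). Per library, the mean level over the list was higher in 5 of 5 heterozygotes than in every wild-type library for the matrix (4.08 ± 0.167 against 3.14 ± 0.083 log2 CPM), macrophage (1.86 ± 0.403 against 0.63 ± 0.222) and fibroblast lists (4.38 ± 0.297 against 3.68 ± 0.161). A two-sided exact permutation test gave p = 0.00794 for each, the smallest that 5 against 5 allows, and 0.0635 when adjusted over the 24 tests of the family. Endothelial (median 0.40, 20 of 20 higher, camera adjusted p = 6.65e-05), pericyte (0.39, 12 of 13, 0.00116), interferon (0.48, 30 of 34, 4.91e-06), inflammation (0.35, 17 of 22, 0.00318) and fetal and wall stress lists (0.33, 22 of 27, 1.66e-05) were also higher as groups. With an estimated correlation their adjusted p = 0.458, 0.276, 0.353, 0.355 and 0.247, in this order. In the stress list 0 genes were called over all genes and 5 over the list alone. Its genes of natriuretic peptides and myosin heavy chains, Nppa (log2 fold change 1.17, SE 0.954), Nppb (0.70, SE 0.382), Myh6 (-0.26, SE 0.166) and Myh7 (-0.24, SE 0.571), were not called.

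Genes of fuel use were lower as groups at 6 months. Of 39 fatty acid oxidation genes, 35 were lower (median -0.32, camera adjusted p = 1.72e-12, adjusted p = 0.247 with an estimated correlation). Eci1 was at -0.57, Acsl1 at -0.50, Decr1 at -0.55 and Acot2 at -0.53, with 0 called over all genes and 9 over the list alone. All 32 genes of the TCA cycle and of branched-chain amino acid breakdown were lower (median -0.25, camera adjusted p = 1.72e-12, adjusted p = 0.276 with an estimated correlation), such as Mccc2 (-0.54) and Idh3g (-0.31). In the oxidative phosphorylation list 61 of 78 genes were lower (-0.10, camera adjusted p = 4.86e-05, adjusted p = 0.609 with an estimated correlation, Sdhc -0.41). The mitochondrially encoded list was higher in 11 of 13 genes (0.53, camera adjusted p = 8.66e-05, adjusted p = 0.391 with an estimated correlation, mt-Co2 0.88). The circadian clock list was lower (median -0.41, 16 of 21 genes, camera adjusted p = 4.08e-07) and stayed so with an estimated correlation (adjusted p = 0.0385). Usp2 was at -0.58, Nr1d2 at -0.57, Bhlhe40 at -0.50 and Per3 at -0.81, with 0 called over all genes and 5 over the list alone. Pdk1, which restrains pyruvate dehydrogenase, fell (-0.58, SE 0.116, edgeR adjusted p = 0.0244) in a glycolysis list that was lower in 18 of 24 genes (-0.07, camera adjusted p = 0.00174, adjusted p = 0.353 with an estimated correlation). Immediate early (-0.40, 22 of 27 lower, camera adjusted p = 0.000338; Jun -0.64), ion channel (-0.14, 31 of 41, 0.00116; Atp2a2 -0.33), sarcomere (-0.12, 18 of 26, 0.00278; Tcap -0.80) and ventricular myocyte lists (-0.19, 16 of 18, 0.000475; Slc2a4 -0.58) were lower. Their adjusted p = 0.276, 0.276, 0.391 and 0.326 with an estimated correlation. Ribosomal protein genes (0.11, 48 of 55 higher, camera adjusted p = 4.99e-05), p53 genes (0.13, 17 of 24 higher, 0.0484; Phlda3 1.52) and erythroid markers (-1.18, 6 of 6 lower, 0.0252; Hba-a2 -2.49) were called too. Their adjusted p = 0.526, 0.276 and 0.33 with an estimated correlation. The sarcomere call was lost without heterozygote 3 (camera adjusted p = 0.074), and the ribosomal call without wild type 3 (0.121). The erythroid call was lost without any of 3 libraries (up to 0.184, without wild type 1) and the p53 call without any of 6 (up to 0.162, without heterozygote 2). The desmosome list was not called for genotype at 3 months, 6 months or with exercise (camera adjusted p = 0.42, 0.613 and 0.527). Its members Jup, Pkp2, Dsg2, Dsc2 and the connexin gene Gja1 were at -0.04, 0.07, -0.15, -0.10 and 0.15 at 6 months, none called.

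Among exercised mice, Dmd and Ctnna3 were again lower in heterozygotes. Dmd fell 3.08-fold, from 408.3 ± 45.6 to 132.7 ± 28.1 CPM (SD, n = 5, log2 fold change -1.62, SE 0.192, edgeR adjusted p = 2.55e-05, 10 of 10 libraries). Ctnna3 fell 2.38-fold, from 55.4 ± 6.49 to 23.3 ± 7.28 CPM (-1.25, SE 0.176, edgeR adjusted p = 0.000172). Immp2l, a mitochondrial inner membrane peptidase, fell 3.18-fold (-1.67, SE 0.267, edgeR adjusted p = 0.00105). Ndrg4 rose 4.12-fold, from 132.4 ± 78.1 to 546 ± 146 CPM (2.04, SE 0.346, edgeR adjusted p = 0.00471), and Ndnf 3.21-fold, from 10.7 ± 1.43 to 34.4 ± 5.32 CPM (1.68, SE 0.245, edgeR adjusted p = 0.000337). Rises were also called for the endothelin gene Edn3 (1.96, edgeR adjusted p = 0.0238), the protease gene Mmp23 (1.90, 0.0399), the matricellular gene Wisp1 (1.71, 0.0166), Dpysl3 (1.57, 0.0056), Adam22 (1.48, 0.00568) and Faap20 (1.21, 0.00769). Falls were called for Amy1 (-1.74, edgeR adjusted p = 0.00914), Macrod1 (-1.52, 0.0497), Polr3g, an RNA polymerase III subunit (-1.202, 0.0352), and Adhfe1 (-1.16, 0.00471). In all, 35 genes rose and 28 fell, and 60 of the 63 were protein-coding. Irs4, named after its values were seen, had 0 counts in wild type and 74 in heterozygotes, at least 27.4-fold higher with the same floor. Heterozygote 4 stood apart for several genes of the cardiac stress response: it had 8370 CPM of Myh7 against 631.3 to 1140 in the other heterozygotes, 1329 CPM of Nppa against 43.7 to 163.6, and 19.6 CPM of Mmp23 against 2.43 to 3.94. Neither Myh7 (log2 fold change 1.95, SE 0.591, edgeR adjusted p = 0.176) nor Nppa (2.95, SE 1.01, edgeR adjusted p = 0.261) was called, and Nppb (0.29), Myh6 (-0.29), Jup (0.00), Pkp2 (0.19), Dsg2 (0.19), Dsc2 (0.08) and Gja1 (-0.07) were not. The 63 calls became 25 without wild type 2 or 4, 27 without heterozygote 4, 40 without wild type 3 and 41 without heterozygote 2. Leaving out 1 library ended the call of Mmp23 (in 5 of 10 fits, highest edgeR adjusted p = 0.423 without heterozygote 4), Edn3 (4, 0.166 without heterozygote 4) and Macrod1 (8, 0.172 without heterozygote 4). It also ended those of Polr3g (7, 0.124 without wild type 2) and Wisp1 (5, 0.0726 without wild type 3).

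By groups, energy metabolism was lower in exercised heterozygotes than in exercised wild type. This held for 75 of 78 oxidative phosphorylation genes (median log2 fold change -0.19, camera adjusted p = 7.05e-12; Ndufc1 -0.43, Cox7a1 -0.53), 33 of 39 fatty acid oxidation genes (-0.26, 4.9e-06; Etfdh -0.42) and 31 of 32 TCA cycle genes (-0.22, 1.97e-08; Hibadh -0.34). With an estimated correlation the adjusted p = 0.616 for each of these 3 lists. Adipogenesis genes (-0.49, 19 of 25 lower, camera adjusted p = 0.000319; Car3 -3.19, Pck1 -3.89) and adipocyte markers (-0.56, 8 of 9 lower, 0.000457; Adipoq -4.38, Cfd -3.61) were lower. Of these lists 0 genes were called over all genes and 7 and 4 over the list alone, and their adjusted p = 0.53 and 0.308 with an estimated correlation. Heat shock genes were lower (-0.25, 21 of 25, camera adjusted p = 1.19e-07; Hspa1b -1.55, Hsph1 -0.71), as were immediate early (-0.27, 19 of 27, 0.000258; Atf3 -1.33, Jun -0.67) and ribosomal protein genes (-0.14, 47 of 55, 0.000356; Rps21 -0.31). Their adjusted p = 0.118, 0.522 and 0.785 with an estimated correlation, and 7, 8 and 0 of their genes were called over the list alone. Fetal and wall stress genes were higher (0.46, 25 of 27, camera adjusted p = 6.44e-06, adjusted p = 0.308 with an estimated correlation). Edn3 was called over all genes and 8 genes over the list alone, and Uchl1 was at 1.60, Mybpc2 at 1.36 and Des at 0.46. The matrix (0.69, 36 of 39 higher, camera adjusted p = 2.8e-06; Timp1 1.89, Comp 3.37), macrophage (0.71, 15 of 15, 0.000421; Adgre1 1.203) and fibroblast lists (0.29, 16 of 17, 0.0125; Postn 1.94) were higher. Their adjusted p = 0.616, 0.616 and 0.785 with an estimated correlation. All 3 calls were lost without heterozygote 4 (camera adjusted p = 0.706, 0.185 and 0.919), and the fibroblast call also without wild type 2 or 3.

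The 3 genotype comparisons share no library. At 6 months, 10 genes were called with the same direction in both activity groups: Ndnf, Pcolce and Irs4 were higher and Dmd, Ctnna3, Exoc2, Prrg1, Amy1, Acot7 and Dcakd lower. Independent lists would share 0.0112 and 0.0287 genes in these directions (two-sided Fisher exact p = 1.03e-07 and 3.03e-16 across genes, which are not independent replicates), and 0 were called in opposite directions. Ndnf alone was called in all 3 comparisons, 4 genes were with the DESeq2 Wald test, and 5 were without the library labelled heterozygote 3, which stood out by such genes. Across 11189 genes, the genotype effects at 6 months with and without exercise had a Pearson correlation of 0.297, and those at 3 months had 0.038 with regular activity and 0.142 with exercise at 6 months. Because a floxed allele carries flanking DNA of its strain of origin, the neighbourhood of Dsp was compared with the rest of the genome. Within 20 Mb, 3 of 259 tested genes were called for genotype (Exoc2 at 7.34 Mb, Hist1h1c and Sfxn1) against 99 of 15327 elsewhere, an odds ratio of 1.80 (95% interval 0.363 to 5.48, Fisher exact p = 0.24).

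Exercise went with large differences in both genotypes, which the spike-in entries also separate from the regular-activity libraries. Among mitochondrially encoded transcripts, mt-Co2 rose 5.64-fold in wild type, from 284.6 ± 54.3 to 1605 ± 926 CPM (SD, n = 5, log2 fold change 2.50, SE 0.329, edgeR adjusted p = 2.66e-05), and 3.65-fold in heterozygotes (1.87, SE 0.321, edgeR adjusted p = 0.000527). Junb, an immediate early transcription factor, fell from 234.5 ± 46.8 to 76.1 ± 21.2 CPM in wild type (-1.62, SE 0.178, edgeR adjusted p = 1.45e-06) and from 176.2 ± 33.8 to 60.3 ± 9.82 CPM in heterozygotes (-1.55, SE 0.178, edgeR adjusted p = 1.87e-06). In wild type, rises were also called for mt-Atp8 (4.13), mt-Atp6 (2.45), which overlaps it, mt-Nd4l (2.41), mt-Nd6 (2.12), mt-Rnr2 (1.90), the signal recognition particle RNA gene Rn7s2 (2.25) and Gcnt1 (2.03). Falls were called for Aph1b (-2.35), Kbtbd13 (-2.26), Emilin2 (-1.91), Rplp1 (-1.79), Gstp2 (-1.79), Gbp6 (-1.75), the cytokine signalling inhibitor Socs3 (-1.73) and Hist1h3e (-1.66). In heterozygotes, rises were called for Mir6236 (4.65), Rn7s1 (2.71), mt-Tp (2.45), Rn7s2 (2.43), mt-Nd6 (1.90), Sstr3 (1.67) and mt-Nd2 (1.504), with falls of mt-Tv (-2.62), the chaperone genes Hspa1a (-2.17) and Hspa1b (-1.97), H2-Ab1 (-1.65), Atf3 (-1.61), Hist2h2ac (-1.55) and Socs3 (-1.54). Rn7s1 and Rn7s2, Hspa1a and Hspa1b, Gstp2, Gbp6, Rplp1 and the histones share sequence with copies, so their values are uncertain. In all, 724 genes rose and 787 fell in wild type, and 833 rose and 542 fell in heterozygotes. The effects correlated at 0.574 across genes, with 413 shared rises (38.7 expected for independent lists), 303 shared falls (27.4 expected) and 1 gene in opposite directions. Without 1 library the call of Gcnt1 was lost in 7 of 10 fits (highest edgeR adjusted p = 0.0934 without 6-month wild type 5), and Gbp6 in 2 (0.0546 without the same library). In heterozygotes the call of Sstr3 was lost in 8 (0.122 without exercised heterozygote 5), mt-Tv in 7 (0.077) and H2-Ab1 in 5 (0.111), both highest without 6-month heterozygote 3, and Socs3 without 6-month heterozygote 1 (0.0626). The 1375 calls in heterozygotes became 897 without 6-month heterozygote 4.

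Of 13 mitochondrially encoded genes tested, 12 rose in wild type and 9 in heterozygotes, and 13 in both when adjusted over the list alone. Their medians were 1.87 and 1.18 (camera adjusted p = 1.46e-16 and 1.06e-11, adjusted p = 0.11 and 0.224 with an estimated correlation). The share of ribosomal RNA was also higher in the exercised libraries (5.31% and 5.12% against 1.82% and 3.52%). Of 27 immediate early genes, 13 fell in each genotype (17 over the list alone), among them Junb, Ier5 (-1.18 and -1.29) and Btg2 (-1.10 and -0.94). The medians of this list were -0.70 and -0.94 (camera adjusted p = 2.39e-10 and 1.06e-11, adjusted p = 0.0968 and 0.0581 with an estimated correlation). Of 55 ribosomal protein genes, 13 fell and 2 rose in wild type and 27 fell in heterozygotes (14 down and 2 up, and 37 down, over the list alone), with Rpl13 at -0.69 and -0.89. The medians were -0.15 and -0.34 (camera adjusted p = 0.000594 and 2.41e-18, adjusted p = 0.922 and 0.224 with an estimated correlation). Of 20 histone genes, 8 and 5 fell (9 and 10 over the list alone), with Hist1h3e at -1.66 and -1.21. The medians were -0.77 and -0.70 (camera adjusted p = 7.02e-06 and 1.57e-06, adjusted p = 0.11 and 0.127 with an estimated correlation).

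Of 78 nuclear oxidative phosphorylation genes, 19 fell and 4 rose with exercise in wild type, and 20 fell and 1 rose in heterozygotes (27 down and 7 up, and 29 down and 3 up, over the list alone). Atp5e was at -0.75 and -0.87 and Cox8a at -0.73 and -0.84. The medians were -0.12 and -0.23 (camera adjusted p = 0.00322 and 1.77e-07, adjusted p = 0.922 and 0.642 with an estimated correlation). Of 26 sarcomere genes, 9 rose and 1 fell in wild type and 10 rose in heterozygotes (9 up and 4 down, and 11 up, over the list alone). Myoz2 was at 0.65 and 0.73 and Tnnt2 at 0.56 and 0.60. The medians were 0.14 and 0.29 (camera adjusted p = 0.036 and 2.13e-05, adjusted p = 0.922 and 0.338 with an estimated correlation). In wild type the sarcomere call was lost without any of 4 libraries (camera adjusted p up to 0.182, without regular-activity wild type 3). The oxidative phosphorylation call in wild type was lost without regular-activity wild type 4 (camera adjusted p = 0.12) or exercised wild type 1.

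In heterozygotes, 7 genes of the desmosome and intercalated disc list rose and 2 fell with exercise (12 up and 2 down over the list alone, of 31, median 0.22, camera adjusted p = 0.00626, adjusted p = 0.224 with an estimated correlation). Ldb3, a Z-disc gene (log2 fold change 0.58, SE 0.084, edgeR adjusted p = 3.32e-05), and Ank3 (0.63, SE 0.1, edgeR adjusted p = 9.15e-05) rose. The N-cadherin gene Cdh2 (0.45, SE 0.096, edgeR adjusted p = 0.00247) and the desmoglein gene Dsg2 (0.49, SE 0.158, edgeR adjusted p = 0.045) rose too. Jup, the plakoglobin gene, fell in heterozygotes (-0.41, SE 0.112, edgeR adjusted p = 0.0185) and in wild type (-0.46, SE 0.112, edgeR adjusted p = 0.00732). Pkp2 (-0.28 in heterozygotes and -0.40 in wild type), Dsc2 (0.37 and 0.19) and Gja1 (-0.34 and -0.12) were not called. Myh7 was called in heterozygotes (1.97, SE 0.591, edgeR adjusted p = 0.0367), with 6 of 10 libraries on their group's side and 8370 CPM in exercised heterozygote 4. Among ion channel and calcium genes 4 of 41 rose (8 over the list alone), such as Ryr2 (0.45) and Casq2 (0.47), with a median of 0.17 (camera adjusted p = 0.0308, adjusted p = 0.562 with an estimated correlation). Among circadian genes 4 rose and 1 fell of 21 (5 and 1 over the list alone), with Usp2 at 0.60 and Arntl at -2.31 and a median of 0.28 (camera adjusted p = 0.00366, adjusted p = 0.224 with an estimated correlation).

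With exercise in heterozygotes, inflammation genes had a median of -0.49 (camera adjusted p = 0.00135, adjusted p = 0.496 with an estimated correlation), with 4 of 22 called down over all genes and over the list alone, such as Relb (-0.85). Interferon genes had a median of -0.69 (camera adjusted p = 1.65e-05, adjusted p = 0.562 with an estimated correlation), with 2 of 34 called down in both ways, such as Psmb9 (-1.34). Matrix genes had a median of -0.38 (camera adjusted p = 2.33e-06, adjusted p = 0.562 with an estimated correlation), with Col6a3 (-1.42) called down in both ways. Fibroblast (-0.39, 15 of 17 lower, camera adjusted p = 0.000996; Col1a1 -0.90), endothelial (-0.49, 19 of 20, 0.00148; Cldn5 -1.26), pericyte (-0.49, 11 of 13, 0.0308; Notch3 -0.68) and macrophage markers (-0.49, 15 of 15, 0.00281; C1qc -1.07) were lower with 0 called. Their adjusted p = 0.584, 0.704, 0.562 and 0.562 with an estimated correlation. Cell cycle genes were lower (-0.24, 20 of 25, camera adjusted p = 0.0378, adjusted p = 0.52 with an estimated correlation) with 0 called in both ways and Mcm2 at -0.71. The 4 marker calls were lost without exercised heterozygote 1 (camera adjusted p = 0.064, 0.0973, 0.172 and 0.0973), and the pericyte call also without regular-activity heterozygote 3 or exercised heterozygote 2. The cell cycle call was lost without any of 6 libraries (up to 0.187, without exercised heterozygote 1) and the ion channel call without any of 5 (up to 0.153, without regular-activity heterozygote 5).

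By the series title exercise reverses dysregulated expression. The genotype by exercise interaction asks if the genotype gap changed. It called 2 genes, both lower: Aqp6 (log2 fold change -13.0, SE 2.12) and the pseudogene Rps2-ps10 (-4.998, SE 0.823), each at an edgeR adjusted p of 0.0172, named after their values were seen. Aqp6 switched between libraries of 1 group, from 0.11 to 15.03 CPM in regular-activity heterozygotes and from 0.47 to 16.9 in exercised wild type, and Rps2-ps10 had 43.8 to 48.8 CPM in exercised wild types 1 to 4 and 0.76 in wild type 5. The DESeq2 Wald test called 8 genes and limma-voom 13, and 765 genes had an unadjusted edgeR p under 0.05 where 779 would by chance. The edgeR count was 0 without 6-month wild type 3, 4 or 5, 6-month heterozygote 2 or exercised heterozygote 1, 2 or 3, 1 without 6-month wild type 2, and 7 without exercised wild type 5.

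Of the 21 genes called for genotype at 6 months with regular activity, 19 had the same sign in exercised mice, 10 were called there in the same direction and 0 in the opposite one by edgeR. The DESeq2 Wald test gave 22 and 1 of 62 genes. Ndnf (log2 fold change 1.65 with regular activity and 1.68 with exercise), Dmd (-1.22 and -1.62), Ctnna3 (-1.06 and -1.25) and Exoc2 (-1.28 and -1.08) lay on the same side of wild type in both. Their interactions were 0.03 (SE 0.341), -0.40 (SE 0.265), -0.19 (SE 0.244) and 0.20 (SE 0.268), each at an edgeR adjusted p of 0.999. Adjusted over these 21 genes alone, chosen on these libraries, 6 had an interaction (0 over all genes). The 6 were Ak4 (-0.57 regular activity, 0.15 exercised), Jph1 (-0.54, -0.04), Apbb1 (-0.74, -0.15), Lman1l (2.49, 0.60), Gm15487 (-3.76, -0.19) and Rps2-ps6 (-3.85, 0.60). Of the 21, 4 were called oppositely for exercise in heterozygotes and 3 with the same sign in wild type. Exercised heterozygotes against regular-activity wild type gave 16 with the same sign and 0 opposite. These contrasts reuse libraries that chose the genes, which favours such signs without exercise effects. The median difference, signed by the 6-month direction, was 1.23 with regular activity, 0.74 with exercise and 0.49 at 3 months. Genes chosen for a large difference shrink in any other libraries, so the 100 genes with the smallest p in 3 + 3 libraries were measured in the held-out 2 + 2, a comparison chosen after seeing the data. Over 100 such splits the median was 0.84 in the choosing libraries, 0.36 in the held-out ones and 0.27 in exercised mice, where it was above 0 in 100 splits and below the held-out value in 81. Genes called in the choosing libraries, which 18 splits had, gave 1.06 held out and 0.50 in exercised mice, below in 12. Without exercised heterozygote 4, 77 genes were called at 6 months and the signed median with exercise was 0.27.

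**Figure D3:**
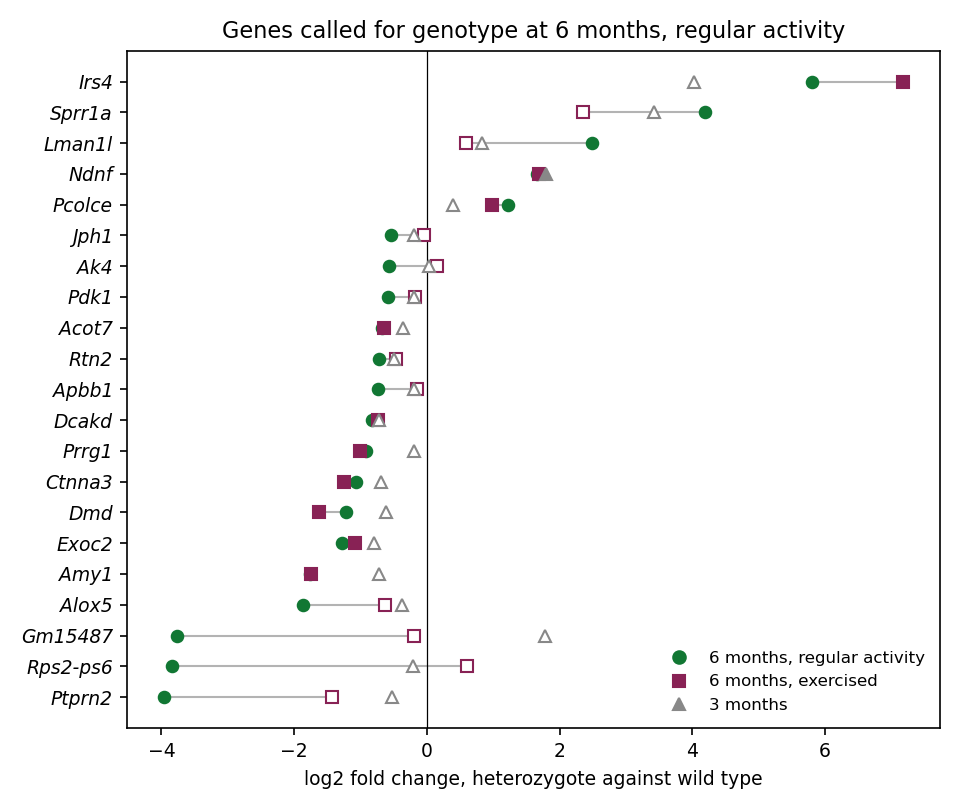
Log2 fold change by genotype (x axis) of the 21 genes called at 6 months with regular activity (y axis), at 6 months with and without exercise and at 3 months (points, filled where the edgeR adjusted p was under 0.05).

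Exercised heterozygotes differed from regular-activity wild type by both effects. Junb fell 3.89-fold (log2 fold change -1.96, SE 0.18, edgeR adjusted p = 2.24e-08, n = 5 per group) and the stress-response factor Atf3 6.18-fold (-2.63, SE 0.348, edgeR adjusted p = 1.53e-05). Falls were also called for the immediate early genes Nr4a1 (-2.14) and Fos (-1.89), Gadd45g (-1.90), Alox5 (-2.00) and the thioesterase gene Acot1 (-2.01), which has near-identical relatives. Rises were called for Mir6236 (4.80), Snord13 (3.42), Map1a (3.29), mt-Co2 (2.75), Rn7s1 (2.74), Fam46b (2.60), mt-Nd4l (2.58) and mt-Nd6 (2.43), and 923 genes rose and 1123 fell in all. The call of Snord13 was lost in 8 of 10 leave-one-out fits (highest edgeR adjusted p = 0.106 without exercised heterozygote 4). Dsp was at 0.11 (SE 0.191, edgeR adjusted p = 0.777), Jup fell (-0.45, edgeR adjusted p = 0.00588), and Nppa (2.92, 0.0569) and Myh7 (1.72, 0.0528) were not called. Of 27 immediate early genes 17 fell (19 over the list alone; median -1.19, camera adjusted p = 8.89e-15), which stayed with an estimated correlation (adjusted p = 0.0181). Mitochondrially encoded genes rose (12 of 13, 12 over the list alone; median 1.75, camera adjusted p = 1.73e-15, adjusted p = 0.206 with an estimated correlation). Of 78 oxidative phosphorylation genes 36 fell and 3 rose (43 and 3 over the list alone), with Atp5e at -1.08 and a median of -0.35 (camera adjusted p = 3.42e-13, adjusted p = 0.71 with an estimated correlation). Of 39 fatty acid oxidation genes 17 fell and 3 rose (18 and 3 over the list alone), with Acads at -1.03, Hadhb at -0.86 and a median of -0.41 (camera adjusted p = 7.9e-06, adjusted p = 0.71 with an estimated correlation). In the TCA cycle list 5 of 32 fell in both ways, such as Idh3g (-0.41), with a median of -0.19 (camera adjusted p = 0.00839, adjusted p = 0.968 with an estimated correlation). Ribosomal protein genes fell (20 of 55, 21 over the list alone, median -0.27, camera adjusted p = 9.83e-09, adjusted p = 0.71 with an estimated correlation). Histone genes fell (5 of 20, 8 over the list alone, Hist1h4h -1.31, median -0.61, camera adjusted p = 0.000247, adjusted p = 0.347 with an estimated correlation). Of 27 fetal and wall stress genes 7 rose and 1 fell (11 and 1 over the list alone), with Pfkp at 1.24, Xirp2 at 1.25 and a median of 0.68 (camera adjusted p = 0.000409, adjusted p = 0.605 with an estimated correlation). The TCA cycle call was lost without exercised heterozygote 4 (camera adjusted p = 0.452).

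Between 3 and 6 months, genes of small structured RNAs fell in both genotypes, sets of libraries that the spike-in entries also separate. In wild type, Rn7s2 fell from 688.1 ± 331 to 94.6 ± 17.1 CPM (SD, n = 5, log2 fold change -2.86, SE 0.264, edgeR adjusted p = 1.49e-07). Falls were also called for Rn7s6 (-4.28), mt-Tv (-4.10), Snora78 (-3.86), Rn7s1 (-2.74), Rmrp (-2.68), Bloc1s1 (-1.85) and the electron transfer gene Etfb (-0.94). Rises were called for Zfp420 (1.27), Rpl23a (1.21), Snx10 (1.18), the ciliary transport gene Ift140 (1.10), Sfxn1 (1.09), Mettl8 (1.01), Zfp28 (0.91) and Mfap1b (0.82), of which Rpl23a and Mfap1b have near-identical copies. In heterozygotes, the complement genes C1qb (2.03, SE 0.573, edgeR adjusted p = 0.0459) and C1qa (2.02, SE 0.544, edgeR adjusted p = 0.0367), the matrix genes Lum (1.82, 7.71 ± 4.71 to 27.6 ± 5.22 CPM) and Dpt (1.70), Meox1 (1.85), Cxcl14 (1.80), Rem1 (1.69) and Cmklr1 (1.64) rose. Snord83b (-5.97), Snora78 (-5.34), Rn7s6 (-4.46), Snora17 (-4.41), Rmrp (-4.11), Snora57 (-4.01), mt-Tv (-3.90) and Vaultrc5 (-3.80) fell. Without 3-month heterozygotes 1 and 2, which had the high small-RNA shares, Snord83b was at -2.57, Snora17 at -1.69, Snora57 at -1.93, mt-Tv at -2.62 and Vaultrc5 at -1.99, all still called. The small-RNA share was 0.118% ± 0.0175 and 0.395% ± 0.380 at 3 months and 0.0857% ± 0.0142 and 0.0779% ± 0.0143 at 6 months, in wild type and heterozygotes. In all, 62 genes rose and 72 fell in wild type and 228 rose and 306 fell in heterozygotes, with 5 shared rises (0.907 expected for independent lists) and 48 shared falls (1.41 expected). The desmocollin gene Dsc2 fell in heterozygotes (-0.51, SE 0.137, edgeR adjusted p = 0.0344). Removing trends on GC content and length, an alternative chosen after seeing the data, moved the median of all genes in heterozygotes by -0.15 and left 2100 calls, of which 362 were up and 1738 down. The wild-type calls became 69, 71 and 75 without 6-month wild types 1, 5 and 4, and 74 and 86 without 3-month wild types 5 and 4. The heterozygote calls became 181 without 6-month heterozygote 3, 345, 341 and 275 without 6-month heterozygotes 1, 4 and 5, 302 without 3-month heterozygote 4, and 327 without the library labelled heterozygote 3. Leaving out 1 library ended calls in wild type for Zfp420 (highest edgeR adjusted p = 0.0932 without 6-month wild type 4), Ift140 (0.095 without 6-month wild type 5), and Mettl8 (0.0529 without 3-month wild type 5). It also ended those of Zfp28 (0.0614 without 6-month wild type 4) and Mfap1b (0.0808 without 3-month wild type 5). In heterozygotes it ended all 8 named rises without 6-month heterozygote 3, with an edgeR adjusted p from 0.0532 (Cxcl14) to 0.138 (Dpt).

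Connective tissue and immune gene groups rose with age in heterozygotes. In the matrix list 10 of 39 genes rose (23 over the list alone), such as Dcn (1.46) and Timp1 (2.30), with a median of 1.26 (camera adjusted p = 2.62e-15, adjusted p = 0.267 with an estimated correlation). Among endothelial markers 4 of 20 rose (20 over the list alone), such as Cdh5 (1.31) and Erg (1.24), with a median of 1.04 (camera adjusted p = 2.59e-11, adjusted p = 0.275 with an estimated correlation). Among fibroblast markers 6 of 17 rose (14 over the list alone), such as Col3a1 (1.60), with a median of 1.36 (camera adjusted p = 2.49e-10, adjusted p = 0.267 with an estimated correlation). Among macrophage markers 4 of 15 rose (10 over the list alone), such as Csf1r (1.53), with a median of 1.46 (camera adjusted p = 1.06e-08, adjusted p = 0.267 with an estimated correlation). Among pericyte markers 2 of 13 rose (6 over the list alone), Vtn (1.32) and Rgs5 (1.29), with a median of 0.86 (camera adjusted p = 0.000317, adjusted p = 0.275 with an estimated correlation). Inflammation (0.61, 16 of 22 higher, camera adjusted p = 0.00609; Osmr 1.38), interferon (0.31, 22 of 34, 0.000298; Oasl2 1.00) and epicardial genes (0.28, 9 of 11, 0.00621; Wt1 1.60) were higher with 0 called over all genes and 2, 0 and 1 over the list alone. Their adjusted p = 0.428, 0.474 and 0.418 with an estimated correlation. Mitochondrially encoded genes were higher (0.65, 12 of 13, camera adjusted p = 0.00275, adjusted p = 0.591 with an estimated correlation), with mt-Co1 (1.02) called over all genes and over the list alone.

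Genes of energy use and contraction fell with age in heterozygotes. Of 78 oxidative phosphorylation genes 15 fell and 1 rose (34 and 2 over the list alone), with Cox5a at -0.74 and a median of -0.28 (camera adjusted p = 2.07e-13, adjusted p = 0.418 with an estimated correlation). In the TCA cycle list 4 of 32 fell (10 over the list alone), with Fh1 at -0.63 and a median of -0.30 (camera adjusted p = 2e-10, adjusted p = 0.35 with an estimated correlation). In the fatty acid oxidation list 5 of 39 fell (7 over the list alone), with Cpt1b at -1.49, Esrra at -0.61 and a median of -0.27 (camera adjusted p = 4.35e-07, adjusted p = 0.399 with an estimated correlation). Of 26 sarcomere genes 4 fell (7 over the list alone), with Tmod1 at -0.41, Tnni3 at -0.55 and a median of -0.27 (camera adjusted p = 7.15e-07, adjusted p = 0.267 with an estimated correlation). Of 18 ventricular myocyte markers 2 fell (8 over the list alone), with Cox8b at -0.75 and a median of -0.29 (camera adjusted p = 8.1e-06, adjusted p = 0.267 with an estimated correlation). Atp2a2, the sarcoplasmic calcium pump, fell (-0.58) as the 1 gene called in both ways of 41 in the ion channel list (median -0.16, camera adjusted p = 0.0018, adjusted p = 0.329 with an estimated correlation). Hk2 fell (-0.41) as the 1 of 24 glycolysis genes called (6 over the list alone, median -0.24, camera adjusted p = 0.00621, adjusted p = 0.428 with an estimated correlation). Ribosomal protein genes were lower (3 of 55 down, 7 down and 1 up over the list alone, Rplp2 -0.96, median -0.10, camera adjusted p = 0.00797, adjusted p = 0.723 with an estimated correlation). Small-RNA genes fell (9 of 17, 9 down and 1 up over the list alone, Rny1 -7.74, median -0.62, camera adjusted p = 1.32e-07, adjusted p = 0.267 with an estimated correlation). The glycolysis and epicardial calls were lost without 3-month heterozygote 4 (camera adjusted p = 0.119 and 0.117), and the ribosomal call without the library labelled heterozygote 3 (0.269) or 6-month heterozygote 2 or 3.

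With age in wild type, 2 of 78 oxidative phosphorylation genes fell and 2 rose (10 and 2 over the list alone), with Ndufc1 at -0.54, Atp5l at 0.71 and a median of -0.13 (camera adjusted p = 2.94e-05, adjusted p = 0.835 with an estimated correlation). Of 55 ribosomal protein genes 4 fell (8 over the list alone), with Rplp2 at -0.75 and a median of -0.13 (camera adjusted p = 2.94e-05, adjusted p = 0.835 with an estimated correlation). Of 26 sarcomere genes 1 fell (3 over the list alone, median -0.19, camera adjusted p = 3.03e-05, adjusted p = 0.741 with an estimated correlation). Ventricular myocyte markers were lower (13 of 18, 0 called and 3 over the list alone, Ckm -0.43, median -0.23, camera adjusted p = 0.00337, adjusted p = 0.835 with an estimated correlation). Of 17 small-RNA genes 4 fell (6 over the list alone), with Rn7sk at -0.63 and a median of -0.36 (camera adjusted p = 2.14e-06, adjusted p = 0.392 with an estimated correlation). The desmosome list was lower (17 of 31, 0 called in both ways, median -0.02, camera adjusted p = 0.0351, adjusted p = 0.741 with an estimated correlation). The desmosome call was lost without any of 4 libraries (camera adjusted p up to 0.1, without 6-month wild type 5).

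The interaction of genotype with age asks if the age gap depends on genotype. Its largest group differences were in matrix genes (median 1.18, 36 of 39 higher, camera adjusted p = 7.44e-15; Mmp14 1.93, Col1a1 1.52), endothelial markers (1.00, 20 of 20, 1.59e-10; Cldn5 1.90), fibroblast markers (1.00, 16 of 17, 2.7e-07) and macrophage markers (1.35, 13 of 15, 3.21e-07; C1qb 2.26). Each had an adjusted p = 0.485 with an estimated correlation. The edgeR test called 0 genes (smallest edgeR adjusted p = 0.0776) with 1253 genes at an unadjusted p under 0.05, limma-voom called 0 and the DESeq2 Wald test 25. The edgeR count was 6 without 3-month heterozygote 4, 2 without 3-month wild type 4, and 1 without the library labelled heterozygote 3 or without 6-month wild type 1.

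The other 10 tested lists were called in none of the 10 comparisons (smallest camera adjusted p = 0.0952, Hippo and YAP targets, genotype by age). Of the lymphocyte and neutrophil markers, Cd4, Ighm and Ptprc had enough counts to be tested and were called in no comparison.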

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

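The tests of the exercise differences, of the myocyte share and of the library labelled heterozygote 3 were chosen only after the result was seen, and the chance splits and the test leaving out each library at 6 months were written before. Each measure was searched for 1 library far from the other 4 of its group, and 10 of 106 groups tested had one, where chance gives about 1 in 20. These were the total count of wild type 3 at 6 months (23.1 × 10⁶), the mitochondrial share of wild type 1 at 3 months (15.4%) and of exercised wild type 1 (46.9%), and the small-RNA share of exercised wild type 5 (0.101%) and exercised heterozygote 2 (0.0454%). The median correlation of wild type 2 at 3 months with its group (0.967) also stood apart. Among named genes the libraries far from the others were heterozygote 4 at 3 months for Abi2 (4.58 log2 CPM), the library labelled heterozygote 3 for Ndnf (3.16), wild type 1 at 6 months for Dmd (8.42) and exercised heterozygote 4 for Mmp23 (4.3).

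By the test of the difference itself, the effect of exercise differed between genotypes for Aqp6 (log2 interaction -13.03) and Rps2-ps10 (-5). As groups it differed for sarcomere (camera adjusted p = 0.0344), oxidative phosphorylation (0.0228), mitochondrially encoded (0.0228), glycolysis (0.0246) and circadian genes (4.18e-05). It also differed for adipogenesis (camera adjusted p = 0.00141), matrix (0.0037), interferon (3.98e-05), heat shock (0.00141) and ribosomal protein genes (3.55e-10), and for endothelial (1.28e-05), pericyte (0.0246), macrophage (0.0228) and adipocyte markers (0.0228). The medians ran from -1.02 for adipocyte and -0.80 for endothelial markers to 0.38 for circadian genes. With an estimated correlation none of these 14 lists was called (adjusted p from 0.155 for circadian genes and from 0.819 for the others). Removing trends on GC content and length turned the median of oxidative phosphorylation from -0.072 to 0.016. Leaving out 1 library ended the calls of 9 of these lists, among them sarcomere (camera adjusted p = 0.74), mitochondrially encoded (0.821), matrix (0.542), endothelial (0.0933), pericyte (0.542) and macrophage (0.626) without exercised wild type 1. The others were oxidative phosphorylation without exercised heterozygote 4 (camera adjusted p = 0.784), glycolysis without exercised wild type 5 (0.362) and adipocyte markers without exercised heterozygote 1 (0.1).

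The effect of age differed between genotypes, by the same kind of test, for fetal and wall stress (camera adjusted p = 0.0123), oxidative phosphorylation (0.000606), mitochondrially encoded (0.000419), fatty acid oxidation (0.000935), TCA cycle (6.57e-07) and circadian genes (0.013). It also differed for matrix (7.44e-15), inflammation (0.013) and interferon genes (0.0135), and for fibroblast (2.7e-07), endothelial (1.59e-10), pericyte (0.00172) and macrophage markers (3.21e-07), all camera adjusted p. The medians ran from -0.25 for TCA cycle genes to 1.35 for macrophage markers. None of these 13 lists was called with an estimated correlation (adjusted p from 0.485 to 0.773). The calls of fetal genes (camera adjusted p = 0.0523 without 3-month heterozygote 2), oxidative phosphorylation (0.0816 without the library labelled heterozygote 3), fatty acid oxidation (0.0528 without 3-month heterozygote 4), inflammation (0.083 without 3-month wild type 3) and interferon genes (0.186 without the library labelled heterozygote 3) were each lost when 1 library was left out.

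Libraries were regrouped in 100 ways per comparison, the real grouping among them. For genes, at least the real count was reached in 8 ways for genotype at 3 months (real 30, highest other 69) and in 100 for the genotype by age interaction (0, 4), so chance cannot be excluded for these. It was reached in 1 way for genotype at 6 months (real 21, highest other 3), 2 for genotype with exercise (63, 167), 1 for exercise in wild type (1511, 94) and 1 in heterozygotes (1375, 232). For the genotype by exercise interaction it was reached in 3 ways (2, 4), for exercised heterozygotes against regular-activity wild type in 1 (2046, 17), and for age in 1 in wild type (134, 5) and 1 in heterozygotes (534, 76). Shares under 0.05 argue against chance, but not for the interaction (765 genes at an unadjusted edgeR p under 0.05, 779 by chance). At 3 months and with exercise, regroupings with 69 and 167 calls exceed the real counts, which points to sample structure. The one with 167 sets exercised wild types 1 and 5 and heterozygotes 2, 4 and 5 against the rest, which are the 2 libraries with high Xist and the 3 with the highest mitochondrial share (46.9%, 38.1% and 32.2%). For gene lists, at least the real count was reached in 87 ways for genotype at 3 months (real 2, highest other 13), 5 at 6 months (21, 22) and 48 with exercise (12, 24). It was reached in 83 for exercise in wild type (6, 24), 32 in heterozygotes (17, 23), 48 for the genotype by exercise interaction (14, 25) and 87 for exercised heterozygotes against regular-activity wild type (8, 22). For age it was reached in 48 ways in wild type (6, 16), 9 in heterozygotes (18, 19) and 11 for the interaction (13, 16), so chance cannot be excluded for any count of lists.

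Many genes differed between exercised and regular-activity libraries, such as mt-Co2 and Junb. After trends on GC content and length were removed, 42.9% of the called genes in wild type kept their call and sign, and 62.0% in heterozygotes, which argues against such a bias as the whole cause. A few transcripts taking a larger share would move all other genes alike, but genes called up less genes called down in the other genotype, without mitochondrial and the 10 most abundant other genes, differed with exercise by 0.981 (SE 0.034) in wild type and 0.932 (SE 0.066) in heterozygotes (two-sided exact permutation p = 0.00794 each), which argues against it. All 10 exercised libraries lack any spike-in value while each 6-month regular-activity library has some, so an effect of separate preparation or processing cannot be told apart from one of exercise.

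Matrix, fibroblast and macrophage lists were higher in heterozygotes at 6 months. Endothelial and pericyte markers rose less than macrophage markers (difference -0.839 and -0.854, smallest adjusted exact permutation p = 0.0238 over 6 differences). A lower share of myocytes is left open, since other cell types need not rise alike and ventricular markers fell (-0.183). The camera adjusted p of the 3 lists stayed at or below 3.35e-05 with each library left out, which argues against 1 library with more RNA from other cells. None was called with an estimated correlation (matrix, fibroblast and macrophage adjusted p = 0.247, 0.276 and 0.132 with an estimated correlation). The fibroblast list shares 7 of its 18 members with the matrix list and the macrophage list 0 of 20.

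The library labelled heterozygote 3 at 3 months read nearer to wild type at genes that respond to genotype. Over 61 of the genes called at 6 months it scored -0.138, just above the 3-month wild types (-0.295 to -0.167, other heterozygotes 0.128 to 0.214). Over 9 of the 10 called in both activity groups it was -0.437, within them (-0.604 to -0.352). A wild-type library or animal under a heterozygote label cannot be told apart from little recombination of the floxed allele in a correctly labelled heterozygote, in which Dsp would also stay high (10.14 log2 CPM). A swap with a 3-month wild-type library is argued against, since the highest score among these was -0.167.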

How the results depend on the processing

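Given below are values that left their side of the threshold or moved; the cause was not tested. Fits on GC content and length, on Xist and without 2 libraries were chosen after seeing the data. The number of genes called for genotype at 3 months (30) was 2 without a low-count filter, 5 with 1 surrogate variable, 0 from its own groups, 18 with limma-voom, 145 with the DESeq2 Wald test, 4 without GC and length trends, 6 with Xist as covariate and 1 without heterozygotes 1 and 2. At 6 months (21) it was 11 with 1 surrogate variable, 218 from its own groups, 476 with limma-voom, 62 with DESeq2 and 117 without exercised wild type 1 and exercised heterozygote 4. With exercise (63) it was 13 from its own groups, 194 with limma-voom and 203 with DESeq2. Exercise in wild type (1511) gave 2769 with limma-voom and 759 without GC and length trends, and in heterozygotes (1375) 816 without a filter and 2835 with limma-voom. The genotype by exercise interaction (2) gave 5 without a filter, 0 from its own groups, 13 with limma-voom, 8 with DESeq2 and 0 without those 2 exercised libraries. Exercised heterozygotes against regular-activity wild type (2046) gave 1288 without GC and length trends. Age in wild type (134) gave 44 with 1 surrogate variable, 328 with DESeq2 and 208 without those 2 exercised libraries. Age in heterozygotes (534) gave 341 without a filter, 113 with 1 surrogate variable, 1367 with limma-voom, 982 with DESeq2, 2100 without GC and length trends and 1127 without those 2 exercised libraries. The genotype by age interaction (0) gave 3 with 1 surrogate variable, 5 from its own groups, 25 with DESeq2 and 2 without those 2 exercised libraries. Without GC and length trends, 25 genes rose and 100 fell with age in wild type, and 916 rose and 252 fell with exercise in heterozygotes. Whether more genes rose or fell turned with the setting: for exercise in wild type (724 rose, 787 fell) it was 834 and 719 with DESeq2 size factors, 777 and 726 without mitochondrial and 10 abundant genes, and 403 and 356 without GC and length trends. It also turned in others, such as exercise in heterozygotes (389 and 427 without a filter).

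Dsp in exercised heterozygotes against exercised wild type was no longer called without a filter (-0.895, edgeR adjusted p = 0.0906), from its own groups (-0.875, 0.115), without GC and length trends (-0.927, 0.0535) and without those 2 exercised libraries (-0.961, 0.0691), and Dsp with exercise in heterozygotes was called from its own groups (0.431, edgeR adjusted p = 0.0278). Of 12 alternatives, 6 to 9 ended the call of each named 3-month gene but Ndnf, which was lost from its own groups (edgeR adjusted p = 0.316). Of 13, 7 ended that of Prrg1 and 2 that of Dcakd at 6 months, and 6 that of Mmp23 and 7 that of Macrod1 with exercise. Fits of its own groups ended the call of Alox5 at 6 months and, with exercise, those of Ctnna3 (0.0579), Ndrg4 (0.134), Dpysl3, Amy1, Edn3 (0.237), Wisp1, Faap20, Polr3g and Adhfe1. With age they ended those of Snord83b (0.0519), Snora17 (0.061) and Snora57 (0.0569). With 1 surrogate variable all 8 named rises with age in heterozygotes (0.281 to 0.762) and 6 of 8 in wild type were lost, as were Mir6236, Sstr3, mt-Tv, H2-Ab1 and Socs3 for exercise in heterozygotes. Of the 117 list calls, 2 held with an estimated correlation and 31 with fry, which called 34 lists in all. The signed median with exercise (0.735) was 0.978 with DESeq2 size factors, 1.164 from the 6-month groups alone and 1.164 over genes at an adjusted p under 0.01. Without GC and length trends, list medians moved by over 1.5 times for immediate early (-0.937 to -0.61) and oxidative phosphorylation genes (-0.229 to -0.134) with exercise in heterozygotes. They did for 8 lists with age in heterozygotes, such as ion channels (-0.16 to -0.346) and mitochondrially encoded genes (0.645 to 0.327), and for others. The count of genotype genes shared between comparisons (10) was 26 with DESeq2 and 5 at an adjusted p under 0.01.

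The replicate number as a block gave 1 gene for genotype at 3 months, 11 at 6 months, 0 for the genotype by exercise interaction, -0.862 for Dsp with exercise (edgeR adjusted p = 0.0539), 0.962 for the signed median and 6 shared genes. The numbers do not pair the samples: 5 of 15 same-numbered pairs had a correlation over 0.1 (-0.407 to 0.316), and in 3 the best partner had the same number.

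With each library of a comparison left out, the counts ranged from 1 to 74 (genotype at 3 months), 6 to 19 (6 months, 19 without heterozygote 2), 25 to 89 (exercised, 89 without wild type 1), 1101 to 1357 and 897 to 1423 (exercise in wild type and heterozygotes), 0 to 7 (genotype by exercise), 1581 to 1944 (exercised heterozygotes against regular-activity wild type), 69 to 129 and 181 to 668 (age in wild type and heterozygotes) and 0 to 6 (genotype by age). The log2 difference of Dsp ranged from -0.675 to -0.407 at 3 months, -0.394 to -0.214 at 6 months, -1.033 to -0.811 with exercise, 0.914 to 1.137 and 0.357 to 0.461 for exercise in wild type and heterozygotes, and -0.733 to -0.488 for their interaction. It ranged from 0.044 to 0.224 for exercised heterozygotes against regular-activity wild type, -0.571 to -0.381 and -0.377 to -0.088 for age in wild type and heterozygotes, and 0.08 to 0.376 for their interaction. List calls ranged from 107 to 123, the signed median from 0.267 (without exercised heterozygote 4) to 1.25, and shared genes were 9 without the library labelled heterozygote 3 (5 in all 3 comparisons, 1 with it).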

Other observations

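Counting long genes among the calls was chosen only after the result was seen, and the tests of uncalled long genes were written before they were run. Dmd and Ctnna3 span over 500 kb, which led to the hypothesis that very long genes as a class are lower in heterozygotes. Of 86 tested genes with such a span, 2 were called lower at 6 months (Dmd and Ctnna3) and 6 with exercise (Pard3b, Dmd, Dpyd, Kcnd2, Ctnna3 and Immp2l), and 0 at 3 months. These counts hold the genes that prompted the hypothesis, so they do not test it. For the 80 long genes that were not called, a per-library score against 778 genes of matched level differed between genotypes by -0.061 (SE 0.072, two-sided exact permutation p = 0.762) at 3 months. It differed by -0.028 (SE 0.042, exact permutation p = 0.516) at 6 months and by -0.089 (SE 0.053, exact permutation p = 0.127) with exercise, so a lower level of long genes as a class was left open.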
